A study of Mus musculus with 32 samples.

How the data were processed

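RNA of NIH 3T3 cells, a mouse embryonic fibroblast line, was measured on 2-colour Agilent whole-genome arrays, 32 in all. Per the labels, confluent cultures had received a Bmal1 promoter driving luciferase together with siRNA against Foxo3 or a scrambled siRNA, and their clocks were then synchronized with 30 µM forskolin, which raises cAMP. Cells were harvested 24, 30, 36 and 42 h later, which gave 8 groups of 4 arrays. Each sample was hybridized against 1 common reference, a pool from unsynchronized cells of the same line, and within each group the sample carried Cy3 on 2 arrays and Cy5 on the other 2. The labels speak of 4 experiments and do not say what the 4 share, so p-values measure the spread between these samples, part of which may be technical.

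The deposited scanner files hold, per the file headers, the foreground and local background intensity of both channels for 45220 spots, neither background-corrected nor normalized. Channel 1 is Cy5 and channel 2 is Cy3, per the labels. The scanner, its software, slide positions and scan dates are not given in the sources used here. A second table holds the authors' log2 ratios of the same arrays, 1 value per spot. Set against the scanner values, these deposited log2 ratios ran in the direction sample over reference on every array, with a slope of scanner on deposited values between 1.06 and 1.12 and column medians between -0.0165 and 0.0187. Their normalization is not stated. They served as an alternative.

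The main values were computed from the scanner files with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, statmod 1.5.0). The mean signal of each spot was corrected with its background median by normexp with an offset of 50. Each array was normalized by global loess (span 0.3, 4 iterations) with weight 0 for the 4046 control spots, and ratios were turned to log2(sample/reference) on all arrays. Since no negative controls were marked, the brightest 66.7% of the 41174 remaining probes were kept, those with a mean log2 intensity above 6.50. Gene symbols came from the platform's probe table, which gave 1 symbol to 34186 probes, none to 6988 and several to 0. Of its 18322 symbols, 16254 were current in a RefSeq table of GRCm38.p6, and the others were kept as the table gave them. Each gene was represented by its brightest probe, which left 14845 genes.

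A linear model with the 8 groups and a dye term was fitted to all 32 arrays with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Contrasts were the siRNA difference averaged over the 4 times, the same at each time, an F-test of whether it differed between times, and F-tests of time within each siRNA. Oscillation was fitted as a cosine and a sine of a fixed 24 h period per siRNA, since times 6 h apart over 18 h cannot give a period, and the pair of terms was tested between siRNAs. The 32 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The lists cover the core clock, clock outputs, clock modifiers, FOXO targets and family, insulin signalling, G1/S, G2/M, p53 targets, interferon, NF-kappaB, matrix, SRF and TGF-beta targets, cholesterol, lipid, glycolysis and hypoxia. The others are ER stress, heat shock, NRF2, autophagy and lysosome, ribosomal proteins, oxidative phosphorylation, immediate early genes, histones, glucocorticoid targets, Wnt and Notch, the small RNA pathway, and markers of macrophages, epithelium, endothelium, muscle and fibroblasts. Each Foxo3 probe was also compared per time with a two-sided exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

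The genes named are the Foxo family, all measured core clock genes and the clock outputs that passed. They also include the 12 largest rises and 12 largest falls over all times among genes that passed with 1 sign at all 4 times, and the 3 largest of each at each time. For the F-tests they are the 6 genes with the smallest p, and for each list up to 4 members with the smallest p. Genes known only by a clone or predicted name were skipped, which happened 1 time, among the falls. The comparisons and their tests, the lists, this rule and the alternatives were fixed before the data were examined, apart from the tests and alternatives that the closing section names as chosen later. That does not extend to the closing section's tests of explanations, which, apart from the regrouping of arrays, concern patterns found in the results.

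The steps were tested on simulated data in which 200 of the 14845 genes were changed. Over all times, changes of 0.25, 0.5 and 1 (log2) were recovered in 70.1%, 97.0% and 100% of cases, and at 24 h in 28.4%, 77.6% and 100%. An effect present only at 24 h was recovered by the F-test between times in 5.97%, 52.2% and 98.5%. A time course in scrambled cells was recovered in 28.4%, 80.6% and 100%, and a cosine present in scrambled cells alone in 58.2%, 94.0% and 100%. Of 50 moved lists 50 were called, and 0 unmoved lists. The simulated noise was independent between genes and the lists were random. The simulation therefore does not show how often lists of correlated genes are called falsely.

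Median net signal per array lay between 45.2 and 144 in the sample channel and between 41.8 and 126 in the reference channel. Between 60.1% and 98.7% of probes lay above the brightest 1 of 20 copies of the dim control probe in the sample channel. Arrays of 1 group correlated over genes at 0.784 to 0.887 with the same dye orientation and at 0.647 to 0.755 with opposite orientation, which the dye term takes up. In every group, replicates 1 and 3 carried the sample in Cy3 and replicates 2 and 4 in Cy5. The dye term and the fits of single dye orientations therefore cannot separate dye from those pairs of replicates. The number of arrays limits the precision: the median SE was 0.05 (log2) over all times and 0.09 at 1 time. Alternatives were no background correction, an offset of 16, median centring, scaling between arrays, loess within 16 tiles, the authors' log2 ratios, other brightness filters, the mean over probes, no dye term, a replicate block, array weights, a trended robust prior, single times, single dye orientations, leaving out each array and a threshold of 0.01.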

Results

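Gene expression was measured in synchronized NIH 3T3 fibroblasts transfected with siRNA against Foxo3 or with scrambled siRNA. FOXO3 is a forkhead transcription factor held in check by insulin signalling. The 8 groups, made of 2 siRNAs at 24, 30, 36 and 42 h after forskolin, held 4 arrays each, and 14845 genes were bright enough to be tested. All changes are log2 values of the arrays labelled siFoxO3 minus those labelled scrambled, with the SE of the limma model, over 16 against 16 arrays or, at 1 time, 4 against 4. The study's title asks whether FOXO3 acts on circadian rhythms through Clock.

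The targeted gene was looked at first. Foxo3 was measured by 2 probes, both dim, and they moved in opposite directions by small amounts. The probe at position 8371 of the array changed by -0.08 ± 0.03 (adjusted p = 0.0104) and the probe at position 19307 by 0.17 ± 0.03 (adjusted p = 1.48e-04). Their median net signals were 32.3 in scrambled against 33.4 in siFoxO3 for the first, and 46.8 against 47.4 for the second. The first stood above the dim control probe on 12 and 13 of 16 arrays and the second on 14 and 16 of 16. Per time, two-sided exact permutation tests of 4 against 4 arrays gave p between 0.0286, the smallest such a test can give, and 0.4, and adjusted p between 0.0571 and 0.4. Neither probe lay above the brightness filter, and a knockdown of Foxo3 RNA could not be read from them, so groups are named as they are labelled. Of the other family members, Foxo1 (-0.12 ± 0.05, adjusted p = 0.0655), Foxo4 (-0.02 ± 0.04) and Foxo6 (0.05 ± 0.04) did not pass. Foxo1 passed as lower in 5 alternatives, with -0.14 over its probes, and in 4 of 32 fits with 1 array left out.

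**Figure D1:**
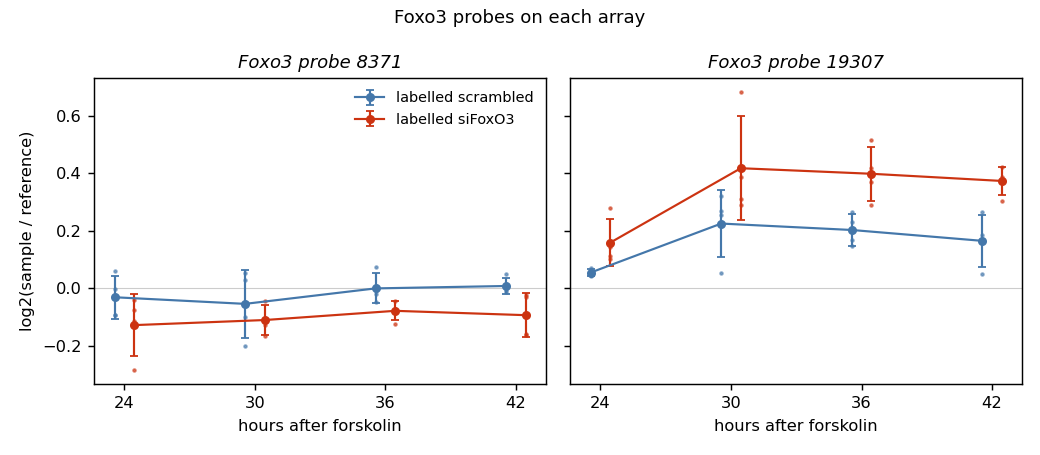
The log2 ratio of sample to reference of both Foxo3 probes is plotted against hours after forskolin, with each of the 4 arrays per group as a small point and the mean with its SD as a large point and bar. In the arrays labelled siFoxO3 the probe at position 8371 lay lower by at most 0.10 at any time, and the probe at position 19307 lay higher by 0.10 to 0.21.

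Over all 4 times, the serum protein genes Saa3, Hp, Saa1 and C3 had the largest rises in the arrays labelled siFoxO3, and the lists of DNA replication and mitosis fell. The largest rise was in Saa3, an acute phase serum amyloid, at 3.13 ± 0.18 or 8.76-fold. Hp, haptoglobin, rose by 2.45 ± 0.04 or 5.47-fold, Saa1, another serum amyloid, by 2.23 ± 0.08, and C3, the central complement component, by 2.12 ± 0.09. Agt, angiotensinogen, rose by 1.85 ± 0.06, Prelp, a leucine-rich matrix proteoglycan, by 1.77 ± 0.03, Steap4, a metalloreductase, by 1.76 ± 0.05, and Cp, the copper carrier ceruloplasmin, by 1.68 ± 0.05. Adm, the vasodilator peptide adrenomedullin, rose by 1.48 ± 0.08, Mt2, a metallothionein, by 1.45 ± 0.13, Lpl, lipoprotein lipase, by 1.42 ± 0.08, and Olfr374, listed as an olfactory receptor, by 1.36 ± 0.05. The largest fall was in Cd109, a cell surface co-receptor for TGF-beta, at -1.33 ± 0.04 or 2.51-fold lower. It was followed by Smc2, a condensin subunit, at -1.11 ± 0.04, Hells, a chromatin remodeller of dividing cells, at -1.10 ± 0.06, and Atad2, a chromatin-bound ATPase, at -1.06 ± 0.06. Gtse1, a G2 and S phase protein, fell by 1.04 ± 0.06, Fam111a, a protease at replication forks, by 1.02 ± 0.05, and Mcm3, part of the replicative helicase, by 1.0 ± 0.06. Ankrd1, a target of YAP and SRF, changed by -1.0 ± 0.05, Dtl, an adaptor that marks replication proteins for degradation, by -0.98 ± 0.06, Depdc1a by -0.98 ± 0.06, and Bub1b, a spindle checkpoint kinase, by -0.97 ± 0.10. Plagl1, a zinc finger growth regulator, changed by -1.06 ± 0.06 on its brightest probe, while its second probe gave 0.08 ± 0.04 and did not pass.

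**Figure D2:**
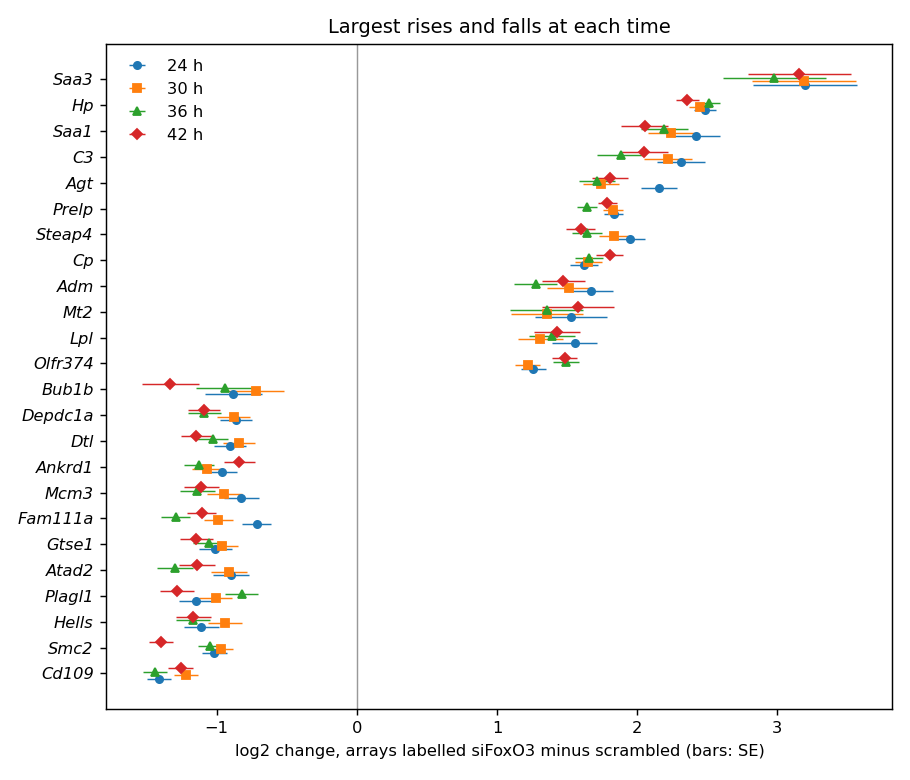
The log2 change between the arrays labelled siFoxO3 and scrambled is drawn on the x axis for the 12 largest rises and 12 largest falls over all times, 1 marker per time, with bars for the SE (4 against 4 arrays). Saa3 lies near 3 at all 4 times and Cd109 between -1.44 and -1.22.

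In all, 5509 of 14845 genes passed over all times, or 37.1%, with 2988 higher and 2521 lower in the arrays labelled siFoxO3. The counts of list members given below, higher and lower together, are to be read against that share. A count in 1 direction is to be read against the 2988 higher or the 2521 lower of 14845. Most changes were small, with a median size of 0.22: 379 genes passed 1.5-fold and 39 passed 2-fold, 31 of them higher and 8 lower. Within the 16 arrays with the sample in Cy3 alone, 3359 genes passed. With the median signal of each spot in place of its mean, 7333 passed.

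All 24 measured G1/S and replication genes fell (median -0.66), and 24 of them adjusted over the list alone. Among them were Uhrf1, which recruits maintenance DNA methylation, at -0.96 ± 0.05, Rrm1, a ribonucleotide reductase subunit, at -0.70 ± 0.04, the origin licensing factor Cdc6 at -0.64 ± 0.03 and Cdc45l, part of the replicative helicase, at -0.53 ± 0.03. Of 26 mitotic genes, 24 fell and 1 rose, both over all genes and adjusted over the list alone (median -0.73). The mitotic kinesin Kif23 changed by -0.95 ± 0.05, the spindle factor Tpx2 by -0.83 ± 0.05, Nusap1, which binds spindle microtubules, by -0.74 ± 0.04 and the checkpoint kinase Ttk by -0.62 ± 0.04. The p53 target list held 9 of 18 genes lower and 3 higher, as many adjusted over the list alone, and was called lower, with adjusted p = 0.0755 with an estimated correlation. Its leading members were Gtse1 and Ckap2 (-0.82 ± 0.07), which are genes of dividing cells, Zmat3 (-0.75 ± 0.06) and the receptor Eda2r (-0.63 ± 0.04).

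The NF-kappaB and cytokine list had the highest median of the raised lists, with 15 of 21 genes higher and 2 lower, as many adjusted over the list alone (median 0.56). Besides Saa3 and C3, the iron-sequestering lipocalin Lcn2 rose by 1.23 ± 0.08 and the apoptosis inhibitor Birc3 by 0.71 ± 0.05. Interferon-stimulated genes were mixed: 11 of 27 were higher and 3 lower, or 12 and 3 adjusted over the list alone. Isg20, an exonuclease, rose by 0.72 ± 0.05 and Rtp4 by 0.36 ± 0.04, while Usp18, which removes ISG15, and Ifit2 both changed by -0.32 ± 0.03, and the list was not called (adjusted p = 0.0842). Macrophage markers held 4 of 11 genes higher and 0 lower, the largest being Cd14 at 0.26 ± 0.06, and the list was not called (adjusted p = 0.469).

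Lysosome and autophagy genes rose, with 16 of 26 higher and 1 lower, or 18 and 1 adjusted over the list alone. They included the proteases Ctsd (0.93 ± 0.09) and Ctsb (0.62 ± 0.04), the membrane protein Lamp2 (0.75 ± 0.06) and the kinase Ulk2 (0.41 ± 0.03). Among glycolysis and hypoxia genes 16 of 27 were higher and 2 lower, or 17 and 3 adjusted over the list alone. Besides Adm, Pdk1, which inhibits pyruvate dehydrogenase, rose by 0.63 ± 0.05 and Ankrd37 by 0.54 ± 0.04, while hexokinase 2, Hk2, changed by -0.52 ± 0.05. Of the lipid and adipocyte genes 10 of 18 were higher and 2 lower, or 11 and 2 adjusted over the list alone. After Lpl came the fatty acid carrier Fabp4 at 0.51 ± 0.04, the desaturase Scd1 at 0.45 ± 0.05 and malic enzyme, Me1, at 0.29 ± 0.04. Fibroblast markers rose in 7 of 12 and fell in 1, or 9 and 1 adjusted over the list alone. The growth factor receptors Pdgfra and Pdgfrb rose by 1.0 ± 0.10 and 0.52 ± 0.07, the surface antigen Ly6a by 0.77 ± 0.10 and the transcription factor Twist2 by 0.46 ± 0.05.

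Of the contractile, SRF and TGF-beta targets 15 of 23 were lower and 4 higher, or 16 and 4 adjusted over the list alone (median -0.22). The matricellular genes Ctgf and Cyr61 changed by -0.45 ± 0.04 and -0.44 ± 0.05, while Ltbp2, which binds matrix microfibrils, rose by 1.14 ± 0.06. Matrix genes were called higher, with 12 of 29 higher and 3 lower, or 13 and 3 adjusted over the list alone, and with adjusted p = 0.116 with an estimated correlation. Thbs2, a thrombospondin, rose by 0.94 ± 0.04 and the collagen gene Col4a2 by 0.57 ± 0.05, while periostin, Postn, changed by -0.67 ± 0.06 and tenascin C, Tnc, by -0.54 ± 0.05.

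Genes described as FOXO targets were on balance higher: 14 of 36 were higher and 4 lower, or 14 and 5 adjusted over the list alone, with adjusted p = 0.0755 with an estimated correlation. Those that rose included the antioxidant enzymes Sod2 (1.0 ± 0.09) and Cat (0.74 ± 0.05), the autophagy gene Gabarapl1 (0.70 ± 0.06) and the mitophagy receptor Bnip3 (0.53 ± 0.05). Glucocorticoid targets held 6 of 11 higher and 2 lower, or 7 and 2 adjusted over the list alone, with adjusted p = 0.0904 with an estimated correlation. Of these, Ampd3, an AMP deaminase, rose by 0.76 ± 0.04 and the phosphatase Dusp1 by 0.55 ± 0.05, while the kinase Sgk1 changed by -0.47 ± 0.06. Clock modifiers held 7 of 20 lower and 1 higher, as many adjusted over the list alone, with adjusted p = 0.116 with an estimated correlation. Of these, Timeless (-0.80 ± 0.05) and Tipin (-0.48 ± 0.05) also protect replication forks, and the kinase Gsk3b and the histone methylation cofactor Wdr5 both changed by -0.21 ± 0.04. Ribosomal protein genes held 7 of 34 lower and 2 higher, as many adjusted over the list alone, with adjusted p = 0.335 with an estimated correlation. Rpl38 changed by -0.45 ± 0.10 and Rpl26 by 0.18 ± 0.04.

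Of the 32 lists, 14 were called over all times by camera, 8 higher and 6 lower, and 8 of them with an estimated correlation. The 6 that were lost are those given with that p.

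**Figure D3:**
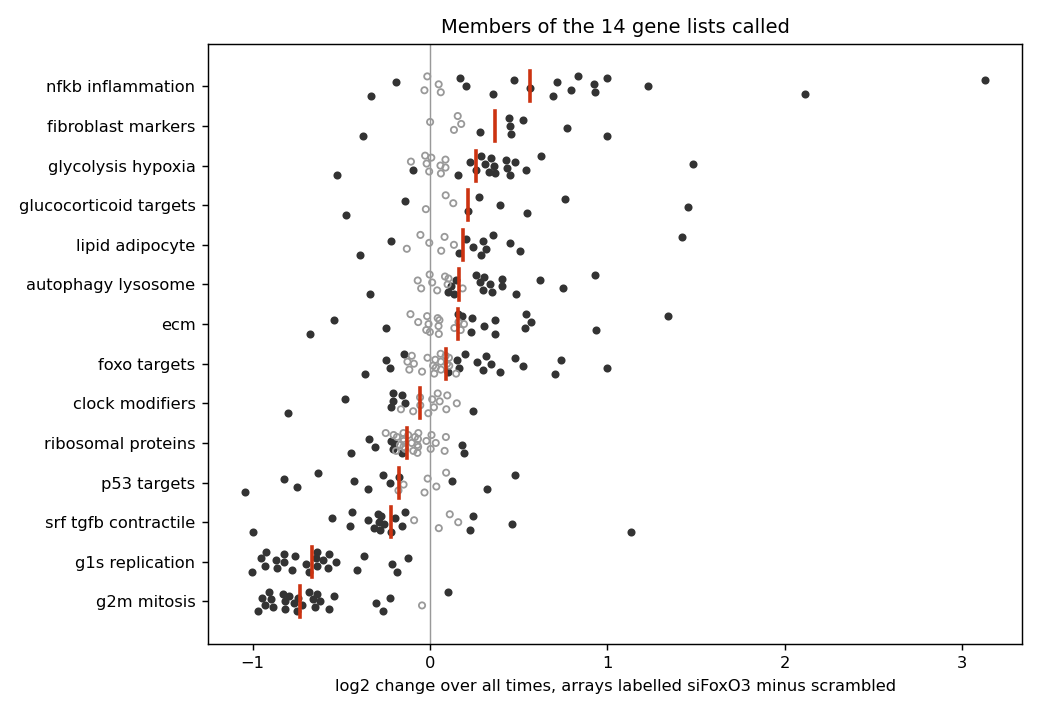
The log2 change over all times between the arrays labelled siFoxO3 and scrambled (x axis) is shown for each measured member of the 14 lists called, 1 line of points per list. Filled points passed the test over all genes, open points did not, and red bars are list medians, from -0.73 for mitosis to 0.56 for NF-kappaB and cytokines.

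The title's question concerns Clock, which encodes a subunit of the activator of the circadian loop. Clock fell by 0.44 ± 0.04 in the arrays labelled siFoxO3 (adjusted p = 1.67e-09), with -0.44, -0.46, -0.49 and -0.36 at 24, 30, 36 and 42 h. Its next 2 probes by brightness gave -0.23 ± 0.04 and -0.14 ± 0.04 and the dimmest -0.03 ± 0.03. Arntl, which encodes the partner BMAL1 and whose promoter drives the transfected reporter, rose by 0.43 ± 0.04. Of the repressors, Cry1 rose by 0.37 ± 0.05 and Cry2 by 0.14 ± 0.03, Per1 fell by 0.14 ± 0.04 and Per3 by 0.15 ± 0.03, and Per2 gave 0.08 ± 0.05 (adjusted p = 0.217), with -0.13 ± 0.04 on its second probe. Nr1d2, which encodes REV-ERB beta, a repressor of Arntl, fell by 0.50 ± 0.04 and Nr1d1 by 0.18 ± 0.06. Rora, which activates Arntl, fell by 0.11 ± 0.04 on its brightest probe, while its next 2 probes by brightness gave 0.47 ± 0.05 and 0.46 ± 0.05. Taken over its probes, Rora gave 0.19, so its direction is open. Among output genes, the PAR bZIP factor Tef fell by 0.62 ± 0.05, Wee1, a mitotic inhibitor kinase, by 0.37 ± 0.04 and Bhlhe40 by 0.10 ± 0.04, while Nfil3 rose by 0.33 ± 0.11, Tsc22d3 by 0.28 ± 0.05, Bhlhe41 by 0.26 ± 0.04 and Hlf by 0.20 ± 0.05. On brightest probes, core clock genes held 6 of 10 lower, Rora with its open direction among them, and 3 higher, and output genes 3 of 10 lower and 4 higher, as many adjusted over the list alone. The calls of Rora, Bhlhe40 and Nr1d1 were lost in 17, 20 and 4 of 32 fits with 1 array left out, and were lost or reversed in 10, 9 and 7 alternatives. The call of Nfil3 was lost in 4 alternatives and those of Per1 and Cry2 in 2 each. Neither list was called over all times (adjusted p = 0.335 and 0.813). The core list was lower at 24 h (median -0.21, adjusted p = 0.0107), where the 4 scrambled arrays are among 5 that stand apart on 23 probes. It was not called at 30, 36 or 42 h (adjusted p = 0.431, 0.694 and 0.568), with 4 genes higher and 2 lower at 36 h. Npas2, Arntl2 and Rorb lay below the brightness filter.

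**Figure D4:**
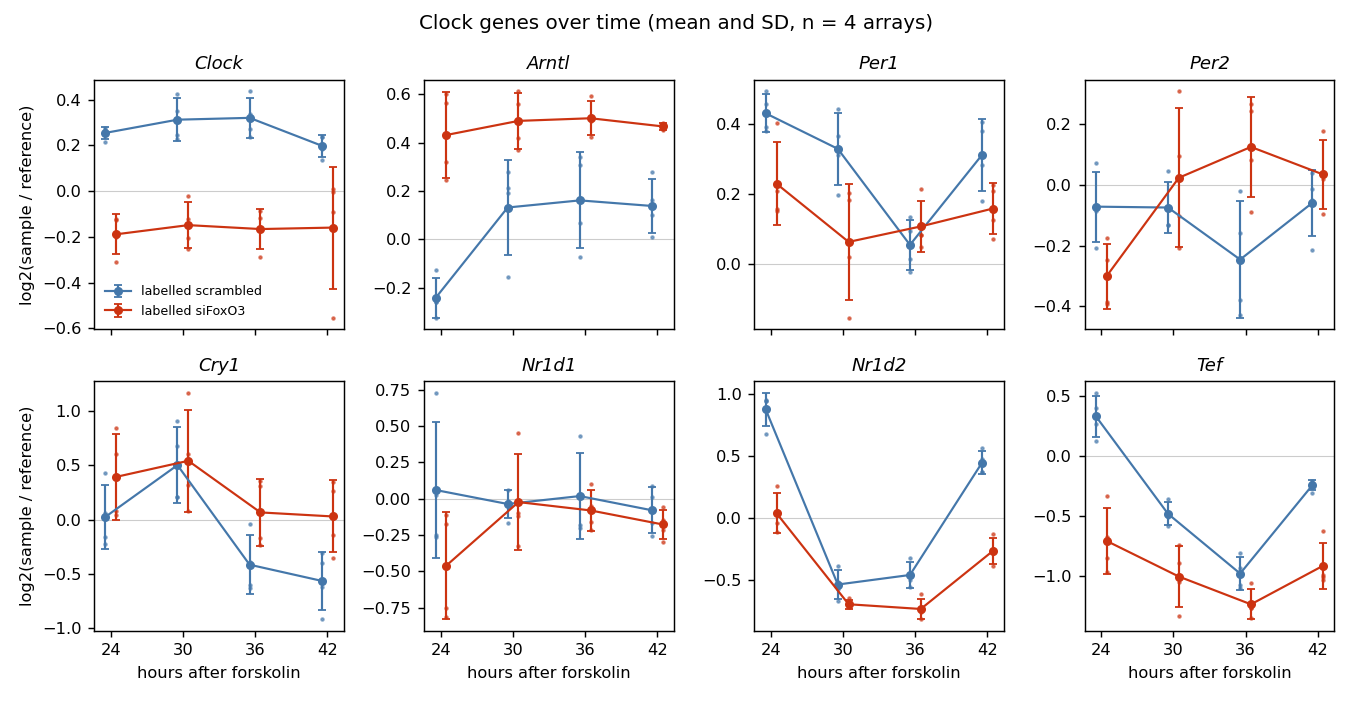
The log2 ratio of sample to reference of 8 clock genes is plotted against hours after forskolin, with each array as a small point and the mean of 4 arrays with its SD as a large point and bar. Clock lies lower in the arrays labelled siFoxO3 at all 4 times, and Nr1d2 falls from 24 h and rises again by 42 h in both arms.

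At single times, Saa3 had the largest rise throughout. It rose by 3.20, 3.19, 2.98 and 3.16 at 24, 30, 36 and 42 h and Hp by 2.48, 2.45, 2.51 and 2.36, each with an SE of 0.37 for Saa3 and 0.08 for Hp. Saa1 was among the 3 largest rises at 30, 36 and 42 h. Cd109 led the falls at 24, 30 and 36 h, with -1.41, -1.22 and -1.44. Hells (-1.11) and Plagl1 (-1.15) followed at 24 h, Ankrd1 (-1.07) and the signal peptidase gene Spcs3 (-1.05) at 30 h, Atad2 (-1.30) and Fam111a (-1.29) at 36 h, and Smc2 (-1.40), Bub1b (-1.33) and Plagl1 (-1.28) at 42 h. Prrxl1, a homeobox gene of sensory neurons, gave a rise of 3.00 ± 0.48 at 24 h alone, and 0.19, -0.06 and 0.33 at the later times, with -0.69 ± 0.29 (adjusted p = 0.137) at 30 h in the fit without the 24 h arrays and scrambled replicate 2 at 30 h. Its log2 ratio to the reference was between -3.42 and -2.99 on the 4 scrambled arrays at 24 h and -3.31 on scrambled replicate 2 at 30 h, and averaged -0.07 on the other 27 arrays. On 23 probes in total the mean of those 5 arrays lay over 2-fold below that of the other 27 with no overlap. For 21 of these, 16 with a symbol, it also lay over 2-fold below the mean of the other 11 scrambled arrays, among them Slc34a2 and Dirc2, both transporter genes, and Pop1, an RNase P subunit.

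At 24 h 2410 genes passed, 1407 higher and 1003 lower, at 30 h 2300 (1150 and 1150), at 36 h 2073 (1013 and 1060) and at 42 h 2300 (1201 and 1099). With the median signal of each spot in place of its mean, 4084, 3985, 3865 and 3989 passed. With median centring in place of loess, the share of higher calls was 29.4% against 50% at 30 h and 78.1% against 48.9% at 36 h. Of the genes that passed over all times, 4976 of 5509 had 1 sign at all 4 times, and 992 genes passed at each of the 4 times, all 992 with 1 sign. Across genes, which are not independent replicates, the changes at any pair of times correlated at r between 0.741 and 0.779 (Spearman's rho 0.602 to 0.651). Without the 24 h arrays and scrambled replicate 2 at 30 h, 1821, 2020 and 2180 genes passed at 30, 36 and 42 h, and 4393 over these times.

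The G1/S, mitosis, NF-kappaB, lysosome, glycolysis, lipid and fibroblast lists were called at all 4 times in the direction given for them. G1/S medians were -0.57, -0.72, -0.66 and -0.79 and mitosis medians -0.64, -0.60, -0.80 and -0.91. Interferon genes were higher at 24 h (10 higher and 1 lower, median 0.13) and 30 h (8 and 2, median 0.20), but were not called at 36 h (5 and 2, median -0.0088, adjusted p = 0.568) or 42 h (3 and 3, median -0.03, adjusted p = 0.915). Matrix genes were higher at 24 h (11 and 2, median 0.26). Over lists and times together, 48 of 128 tests were called, 30 higher and 18 lower, and 38 with an estimated correlation.

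Whether the difference changed with time was tested gene by gene. It did for 4 of 14845 genes, and 986 had an unadjusted p under 0.05. Retnla, a secreted resistin-like protein, rose by 1.46, 0.92, 0.60 and 0.41 at 24, 30, 36 and 42 h (adjusted p = 1.09e-04). Nr1d2 fell by 0.84, 0.16, 0.28 and 0.71 (adjusted p = 0.00174). Clic5, an intracellular chloride channel protein, went from 0.52 to -0.13, -0.19 and -0.37 (adjusted p = 0.00919). Its call was lost in 4 alternatives and in 3 of 32 fits with 1 array left out. Aldh1l2, a mitochondrial folate enzyme, went from 0.39 and 0.50 to 0.03 and -0.21 (adjusted p = 0.0304, lost in 16 of 32 fits with 1 array left out). Next came Tef and the activin subunit Inhba, both at adjusted p = 0.185. Without scrambled replicate 2 at 30 h, 18 genes passed, and without it and the 24 h arrays 0 passed in limma, with Retnla at adjusted p = 0.540 and Nr1d2 at 0.356.

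Time courses were compared within each arm, and the genes named here are among those with the smallest p. Egr1, a zinc finger factor, was 3.83-fold higher at 24 h than at 42 h in scrambled and 3.34-fold in siFoxO3 arrays, and Egr2 2.93-fold and 2.18-fold. Fos, a subunit of AP-1, was 2.28-fold and 2.14-fold higher, the orphan receptor gene Nr4a1 2.71-fold and 2.36-fold, and Cyr61 3.56-fold and 3.79-fold. Clu, the extracellular chaperone clusterin, went the other way, with -0.99 in scrambled and -1.22 in siFoxO3 arrays at 24 h against 42 h. All 6 passed in both arms, with adjusted p of at most 1.84e-09. In scrambled arrays 334 genes changed with time and in siFoxO3 arrays 161. With the median signal of each spot in place of its mean, 977 and 649 did, and with median centring in place of loess 191 and 58. Over 30 to 42 h alone, and without scrambled replicate 2 at 30 h, 20 and 8 did. Egr1 (adjusted p = 0.299 in scrambled and 0.320 in siFoxO3), Egr2, Fos and Cyr61 then did not pass in either arm and Nr4a1 did not in scrambled arrays, while Clu passed in siFoxO3 arrays. Without replicate 2 or replicate 4 of siFoxO3 at 24 h, 101 and 96 genes changed in siFoxO3 arrays.

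**Figure D5:**
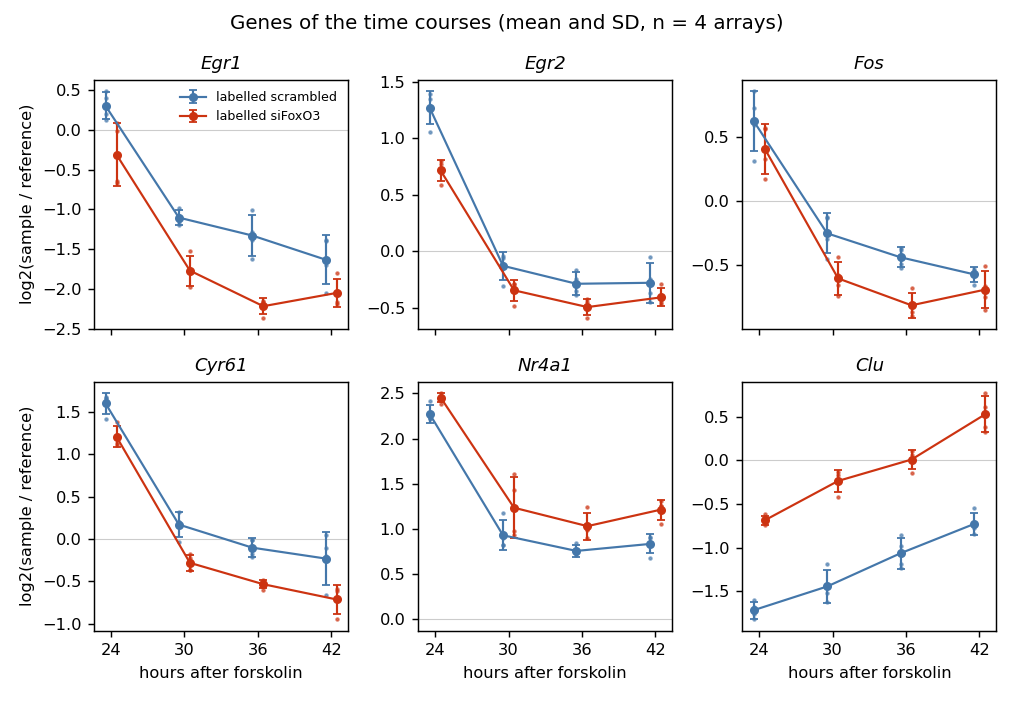
The log2 ratio of sample to reference of 6 genes is plotted against hours after forskolin, with each array as a small point and the mean of 4 arrays with its SD as a large point and bar. Egr1, Egr2, Fos, Cyr61 and Nr4a1 lie highest at 24 h in both arms and Clu lies highest at 42 h.

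Rhythms were described by a 24 h cosine in each arm. Nr1d2 had an amplitude of 0.83 in scrambled and 0.44 in siFoxO3 arrays (log2, SE of each term 0.05), Tef 0.67 and 0.27 (SE 0.05), Cry1 0.58 and 0.30 (SE 0.05) and Cry2 0.19 and 0.03 (SE 0.04). These 4 genes differed between the arms, adjusted over the list alone (adjusted p = 2.80e-04, 2.45e-04, 0.0210 and 0.0408). For Cry2 this was lost in 12 of 32 fits with 1 array left out. Fitted peaks are phases within the fixed 24 h cycle counted from forskolin, so a value such as 4.51 h recurs 24 h later. They lay at 21.6 h and 22.1 h for Nr1d2, 23.3 h and 23.4 h for Tef, and 4.51 h and 3.83 h for Cry1. For Cry2 the peak lay at 1.08 h in scrambled arrays. No oscillation of Cry2 passed in siFoxO3 arrays (F-test, adjusted p over the list alone = 0.804), so the fitted 3.89 h there cannot be read as a peak. The second Cry1 probe gave 0.38 and 0.12. The fifth gene was Per2, whose brightest probe gave 0.09 and 0.21 (adjusted p = 0.0111) while its second probe gave 0.51 and 0.17, so the direction for Per2 depends on the probe. Of the 20 core clock and output genes, 8 oscillated in scrambled arrays and 8 in siFoxO3 arrays, adjusted over the list alone, and 10 had the lower amplitude in siFoxO3. Only Cry1, Nr1d2 and Tef were in both sets. Arntl, Per1, Per3, Cry2 and Bhlhe40 passed in scrambled arrays alone, and Per2, Nr1d1, Hlf, Wee1 and Nampt in siFoxO3 arrays alone. For Nr1d1 the amplitudes depended on the probe: 0.03 and 0.20 on the brightest, 0.03 and 0.05 on the next, and 0.27 and 0.05 on the dimmest. Over all 14845 genes, 264 and 90 oscillated and 0 differed between the arms in limma, with 1016 at an unadjusted p under 0.05. Of the 5 genes, 2 differed over 30 to 42 h without scrambled replicate 2 at 30 h, Nr1d2 and Cry1. Without scrambled replicate 1 or siFoxO3 replicate 3 at 30 h, 3 of the 20 genes differed.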

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

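The tests of a label exchange, of the correlation between dye orientations and of a batch shared by 5 arrays, over all clock genes and gene by gene, were chosen only after the result was seen. The other tests of explanations, apart from the regrouping of arrays, also address patterns that were found in the results.

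Foxo3, the targeted gene, did not show a clear fall: 1 probe changed by -0.08 and the other by 0.17. Dim signal may account for this, since 143 dim probes of 108 genes, each with a brighter probe that changed, showed a median of only 0.0896 of the change on the bright probe (quartiles 0.0122 to 0.205). An exchange of the siRNA labels between the arms cannot be told apart from this, because the probe with the larger change rose by 0.17 and the FOXO target list, with 14 of 36 genes higher and 4 lower in the arrays labelled siFoxO3, runs with an exchange without deciding it (adjusted p = 0.0313, and adjusted p = 0.0755 with an estimated correlation). Whether FOXO3 protein fell was not measured on these arrays.

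The breadth of the siRNA difference, 5509 genes over all times, was weighed next. A dye bias common to both arms cancels in the difference, since each group held 2 arrays of each orientation. A difference confined to 1 dye orientation is argued against by the agreement between Cy3 and Cy5 samples. Their differences correlated at 0.874 over genes, with 2441 of 2444 shared calls in 1 direction. A batch shared by the 4 scrambled arrays at 24 h and scrambled replicate 2 at 30 h is argued against as the whole cause, since 4393 genes passed without the 24 h arrays and that array. A handling or slide batch that follows the siRNA cannot be told apart from the siRNA, because 0 columns of the scanner files name a slide, barcode or date. The siRNA itself, through FOXO3 or through other RNAs it binds, stays open, as only 1 siRNA label against Foxo3 is in the design.

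The smaller amplitude of Nr1d2, Tef, Cry1 and Cry2 in the arrays labelled siFoxO3 was the third pattern. Compression of all ratios on those arrays is argued against, because the time course of 647 genes outside the clock lists had a median ratio between the arms of 0.894, against 0.518 over 13 clock genes. The batch shared by the 5 arrays is argued against as the whole cause for 2 of the 5 genes that differed: without the 24 h arrays and that array, the siFoxO3 time course was 0.487 of the scrambled one for Nr1d2 (adjusted p over the list alone = 9.60e-04) and 0.451 for Cry1 (0.0480). For Tef and Cry2 the ratios were as low, at 0.442 and 0.399, with a median of 0.452 over clock genes, but with fewer arrays the differences did not pass (0.0772 and 0.845), which leaves the batch open for these. A smaller rhythm stays open as a biological explanation, and a changed period was not tested, as the times cannot give one.

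Chance as the source of each count was tested by regrouping the arrays, and for all 11 counts only 1 split, the real one, gave a count as large. That argues against chance between single arrays. Regrouping treats the arrays as independent, and the labels do not say what the arrays of a group share, so chance between cultures could not be judged. Real count and highest other were 5509 and 3663 over all times, 2410 and 18 at 24 h, 2300 and 51 at 30 h, 2073 and 6 at 36 h, and 2300 and 27 at 42 h. They were 4 and 1 for a difference between times, 334 and 36 for time in scrambled, 161 and 12 for time in siFoxO3, and 5 and 2 for clock gene oscillation. For lists they were 14 and 13 over all times, a narrow margin, and 48 and 38 at each time. The other splits over all times called a median of 2 lists. Each time had 35 splits and the other counts 100. The split with 3663 genes had kept 28 of 32 arrays on their own side, as had a split with 13 lists.

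The siRNA difference varied between times for Retnla (adjusted p = 1.09e-04), Nr1d2 (0.00174), Clic5 (0.00919) and Aldh1l2 (0.0304). Oscillation differed between the siRNAs, adjusted over the list alone in limma, for Tef (2.45e-04), Nr1d2 (2.80e-04), Per2 (0.0111), Cry1 (0.0210) and Cry2 (0.0408). In 6 of 176 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20. Cry2 in scrambled replicate 4 at 30 h lay at 0.21 against a median of 0.09 (gap over range 0.848), and Nr1d2 in scrambled replicate 2 at 24 h at 0.67 against 0.94 (0.967). Tef in siFoxO3 replicate 3 at 42 h lay at -0.62 against -1.01 (0.902), and Tsc22d3 in scrambled replicate 1 at 30 h at -0.27 against -0.17 (0.928). Bhlhe40 lay at -0.22 against -0.25 in siFoxO3 replicate 4 at 30 h (0.963) and at -0.55 against -0.24 in siFoxO3 replicate 3 at 36 h (0.85).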

How the results depend on the processing

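The tests with the spot median and without the 24 h arrays and scrambled replicate 2 at 30 h were chosen only after the result was seen. Testing each Foxo3 probe beside the genes kept was also chosen after seeing the data, since both lay below the filter; the alternatives it was run under were otherwise planned. Of 1832 gene values under alternatives, 1754 kept their status as called or not called, 64 lost and 10 gained the call and 4 reversed. A change of sign counted as a reversal only where the value was called before or after it, and F-tests have no sign. Values not called may therefore have changed sign and still count as kept. With 1 array left out, 2608 of 2688 kept their status. Calls lost in several settings include Rora (10 alternatives, 1 of them the reversal, and 17 of 32 fits with 1 array left out), Bhlhe40 (9 and 20), Nr1d1 (7 and 4), the Aldh1l2 difference between times (6 and 16; adjusted p 0.00739 to 0.122 with 1 array left out), the Cry2 amplitude (5 and 12) the clock modifier list (12 and 15) and the ribosomal list (7 alternatives). Of 640 list values 595 kept their status, and of 1024 with 1 array left out 1009. The reversed values were Rora at 0.19 and the Per2 amplitude difference at -0.26 with the mean over a gene's probes, and Prrxl1 at -0.14 and the Per2 amplitude difference at -0.091 without the 24 h arrays and that array. At an adjusted p under 0.01, where fewer calls follow from the threshold, 1510, 1343, 1306 and 1380 genes passed at 24, 30, 36 and 42 h, 165 and 60 changed with time in scrambled and siFoxO3, 2 clock genes differed in oscillation, 9 lists were called and the Foxo3 probe at 8371 (-0.083) did not pass. Median centring gave 2 genes that differ between times and 191 and 58 that change with time; no dye term gave 2, 216 and 78, and 3 clock genes; the cause was not tested. The spot median gave 7333 genes over all times and 4084, 3985, 3865 and 3989 at the 4 times. It also gave 28 that differ between times and 977 and 649 that change with time, and the cause was not tested. With fewer arrays, Cy3 samples alone gave 3359 genes over all times and -0.067 for the Foxo3 probe at 8371, and Cy5 samples alone gave -0.099 for it and 0.14 for the probe at 19307, none of these 3 Foxo3 values passing. Without the 24 h arrays and that array, 0 genes differed between times (limma), 20 and 8 changed with time, 2 clock genes differed, 30 of 96 list tests at single times were called (33 of 96 at these times with all arrays) and the probe at 8371 gave -0.073. An estimated correlation left 8 lists over all times, and fry called 26 over all times and 76 at single times. With 1 array left out, genes that differ between times ranged from 2 (without scrambled replicate 4 or siFoxO3 replicates 1 or 2 at 24 h) to 18 (without scrambled replicate 2 at 30 h), with 7 without siFoxO3 replicate 1 at 30 h. Clock gene oscillation ranged from 3 (without scrambled replicate 1 or siFoxO3 replicate 3 at 30 h) to 6, and genes that change with time in siFoxO3 from 96 (without its replicate 4 at 24 h; 101 without replicate 2) to 179; the cause was not tested. Genes over all times ranged from 5319 to 5484. Replicate number as a replicate block gave 5573 genes over all times. A slide term and plain normalized signals were not run, as the files hold neither. Dim signal limits both Foxo3 probes, whose median net signals were 32.3 and 46.8 in scrambled arrays against 89.0 for the median array.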

Other observations

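Several lists held genes past the threshold without being called over all times. As 37.1% of all genes passed in either direction, higher and lower counts that together lie near or below that share are not a result about a list. For 1 direction the background is 2988 higher and 2521 lower of 14845 genes. Of 14 heat shock genes 5 rose and 2 fell, with the small heat shock genes Cryab at 0.55 ± 0.05 and Hspb8 at 0.42 ± 0.05 and the HSP70 relative Hspa4l at 0.44 ± 0.03 (adjusted p = 0.152 for the list). Among ER stress genes 10 of 26 rose and 5 fell, or 11 and 5 adjusted over the list alone (adjusted p = 0.180). The stress factor Ddit3 rose by 0.60 ± 0.06, the chaperone gene Dnajb9 by 0.51 ± 0.06 and the pseudokinase gene Trib3 by 0.38 ± 0.05, while the serine pathway enzyme Shmt2 changed by -0.41 ± 0.06. That list was called higher at 24 h, with adjusted p = 0.0516 with an estimated correlation. NRF2 and antioxidant genes held 10 of 24 higher and 5 lower, or 11 and 6 adjusted over the list alone (adjusted p = 0.248), with the metallothionein Mt1 at 0.99 ± 0.08 and Gclc, of glutathione synthesis, at -0.37 ± 0.05. Wnt and Notch genes held 6 of 18 higher and 4 lower, or 7 and 4 adjusted over the list alone (adjusted p = 0.679): the secreted Wnt inhibitor Sfrp1 rose by 0.64 ± 0.04, while Wisp1 changed by -0.90 ± 0.06, the Notch ligand Jag1 by -0.84 ± 0.06 and the Notch target Hes1 by -0.39 ± 0.03.

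Immediate early genes held 6 of 24 higher and 7 lower (adjusted p = 0.887), with Egr1 at -0.65 ± 0.06 and Myc at -0.53 ± 0.07. Histone genes held 3 of 11 higher and 3 lower, or 4 and 3 adjusted over the list alone (adjusted p = 0.745), among them Hist3h2a at 0.77 ± 0.05 and Hist1h2aa at -0.63 ± 0.08. Insulin signalling held 6 of 23 higher and 5 lower (adjusted p = 0.679), with the mTORC1 inhibitor Tsc2 at 0.29 ± 0.04, and cholesterol synthesis 4 of 18 higher and 2 lower (adjusted p = 0.887), with lanosterol synthase, Lss, at 0.47 ± 0.05. Oxidative phosphorylation held 3 of 33 higher and 2 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.864). The small RNA pathway held 3 of 13 higher and 2 lower, or 3 and 4 adjusted over the list alone (adjusted p = 0.727), and Rnasen in it is among the 16 named genes low on 5 arrays. Of the markers of other cell types, 2 of 8 epithelial genes rose (Krt14, 0.24 ± 0.04; adjusted p = 0.679), 2 of 8 endothelial genes rose (Vwf, 0.13 ± 0.03; adjusted p = 0.326), and of 12 muscle genes 3 rose and 2 fell (Acta1, -0.73 ± 0.05; adjusted p = 0.887). The FOXO family list held 0 of 3 genes past the threshold in limma (adjusted p = 0.773).

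One hypothesis was that cells labelled siFoxO3 lie further along the difference between these confluent, synchronized cells and the reference pool. It predicts a positive correlation between scrambled over reference and the siRNA difference, taken from separate replicates. The correlation over genes was -0.249 (-0.245 without both cell cycle lists), so the predicted sign was not seen. Whatever all scrambled arrays share enters both sides with opposite sign and lowers the correlation, also between separate replicates. The test therefore cannot decide this hypothesis. A second hypothesis was that the whole clock runs with a smaller amplitude. Of 13 clock genes that oscillate in both arms together, 8 had the smaller amplitude in siFoxO3 (exact binomial p = 0.581, two-sided), so it stays open. These 8 were the core clock genes Arntl, Per1, Per3, Cry1, Cry2 and Nr1d2 and the outputs Tef and Bhlhe40. The larger amplitudes were all in outputs, namely Hlf, Wee1, Nampt, Usp2 and Tsc22d3. Of these, 0 differed between the arms adjusted over the list alone, while the smaller amplitudes of Nr1d2, Tef, Cry1 and Cry2 did. The binomial test ignores the size of each difference and takes the genes as independent, which clock genes on the same arrays are not. Per2 and Nr1d1, whose amplitudes depended on the probe, were not among the 13. The test pooled both lists, and a smaller amplitude of the core genes alone was not tested.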
